A study of Zea mays with 6 samples.

How the data were processed

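Messenger RNA was profiled by Illumina sequencing in maize (Zea mays) at 15 days after pollination, in 3 wild-type (WT) libraries and 3 libraries of homozygous o11 mutants. The sample labels name the tissue as kernel, while the series design text speaks of endosperm. Total RNA was extracted with Trizol, cleaned on a column with DNase I treatment and made into Illumina libraries, per the labels' protocols. The libraries of each genotype carry the replicate numbers 1, 2 and 3. No label says whether they came from separate plants or ears, so p-values measure the spread between these libraries, which may be partly technical.

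The deposited values are FPKM, fragments scaled by locus length and by the mapped fragments of the library, per the file headers, with 1 value per locus and library. Per the submitters' processing notes, Bowtie 0.12.2 was listed for the replicate 1 libraries of both genotypes, and TopHat and Cufflinks, without versions, for the replicate 2 and 3 libraries. The genome build was B73 RefGen_v3 for all 6 libraries, per the same notes. The annotation, read length, strand setting and any further scaling between libraries were not given in the sources used here. Replicate 1 was therefore regarded as a possible processing batch that holds 1 library of each genotype. The fit without the replicate block had no term for it. A term for replicate 1 alone was run as an alternative.

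Each file held 32666 loci, given by chromosome, start and end on B73 RefGen_v3 without gene identifiers. Starts as deposited count from 0 and are printed here counted from 1. Of these loci, 64 lay on the mitochondrial and 34 on the plastid genome, and 117 on scaffolds. In addition, 1879 loci shared their interval with another, over 915 intervals. The reference table at hand lists genes of another build, and coordinates were not converted between builds, so loci were not paired with gene names. Of 26 gene lists fixed before the data were examined (storage proteins, starch synthesis, cell type markers, stress and transcription factor families among them), only the list of plastid and mitochondrial genome loci could be matched, by chromosome name. The other lists, the transcript of the mutated gene and the alternative that leaves out its chromosome were not analysed here. Reads shared between near-identical copies can be divided between loci in ways that the sources do not describe, so single loci inside gene clusters are uncertain and cluster sums are given.

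The number of sequenced fragments is not known. FPKM sums per library were 847961, 947585 and 1072271 in WT replicates 1 to 3, and 784761, 834429 and 1001869 in o11 replicates 1 to 3. The steps between low values, taken from loci under 0.3 FPKM in WT replicate 1 with a tolerance of 0.04 on the log2 scale, gave relative depths of 1.12 and 1.04 for WT replicates 2 and 3 and of 0.897, 1.31 and 1.13 for o11 replicates 1 to 3, with WT replicate 1 set to 1. A value of 0 can be a failed estimate: 42 loci had at least 50 FPKM in 1 library and 0 in another, so a locus is said only to be listed at 0.

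Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, for the 22314 loci with at least 1 FPKM in at least 3 libraries. Changes are on this scale, which understates the change of low loci. The model held genotype, and p-values were adjusted over all loci by the Benjamini-Hochberg method with a threshold of 0.05. Whether replicate numbers pair the libraries was decided from the deviations of each library from its genotype mean, over loci: same-numbered WT and o11 libraries correlated at 0.75, 0.67 and 0.76 (Pearson's r) for numbers 1, 2 and 3, and each number differed from the others. All 3 exceeded the limit of 0.1, so the numbers were taken to pair the libraries. This pairing comes from the data, not from the labels. Values from the fit with the replicate number as a block are given beside those from the fit without it wherever the block changed a call or a count.

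Comparisons of 1 value between genotypes used two-sided exact permutation tests, which cannot give less than 0.10 for 3 against 3 libraries. The organelle list was tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. Named loci were to be those past the threshold with non-overlapping groups, at least 5 FPKM in the higher group and the largest changes, among loci paired with a gene name. With no names at hand, only the 2 largest rises and 2 largest falls are named, out of 99 and 52 loci that met the other conditions. Clusters of abundant loci were defined after the values had been seen, as at least 3 loci with a mean of at least 300 FPKM and gaps of at most 200 kb. Each cluster's summed FPKM was fitted among the loci. Changed loci were counted in 10-Mb windows with at least 20 tested loci and compared with 10000 shuffles of the calls over loci.

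The fit was tested on simulated data for the o11 against WT comparison, with 200 of 22314 loci changed. At a log2 change of 1, 0 of 200 were recovered with or without the block. At a log2 change of 2, 145 (72.5%) were recovered without and 179 (89.5%) with the block, with 1 and 7 unchanged loci called. These shares do not carry over to the data, since the adjusted threshold is stricter when few loci change. In the data, the 4276 loci called with the block had a median absolute log2 change of 0.66. Alternatives covered normalization, the trend, filters, the pseudocount, a test against a fold of 2, single libraries left out, replicate 2 and 3 libraries alone, terms for replicate 1 or 3, and the 50 most abundant loci left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.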

Results

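Transcript levels were compared between WT and o11 mutant maize at 15 days after pollination, when the endosperm, the tissue that stores starch and protein in the kernel, is filling. The opaque11 (o11) gene encodes a basic helix-loop-helix transcription factor of the endosperm. The comparison asks which transcripts depend on the genotype, with 3 libraries per genotype. Between 20995 and 22493 of the 32666 loci reached 1 FPKM in a library, and between 2747 and 4248 were listed at 0. Summed FPKM and the number of loci at 0 were both lower in the o11 library in all 3 replicate pairs (exact permutation p = 0.4 each, without pairing). The number of sequenced fragments behind each value is not known.

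Component 1 of the log2 values (48.0% of the variance) set the replicate 3 libraries of both genotypes apart from the other 4, with scores of 62.8 (WT) and 71.5 (o11) against -51.3 to -17.7. Component 2 (29.5%) separated the genotypes, with WT libraries at -54.7 to -11.2 and o11 libraries at 23.8 to 46.3. In each of the 3 replicate pairs the o11 library lay higher on component 2 than the WT library.

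**Figure D1:**
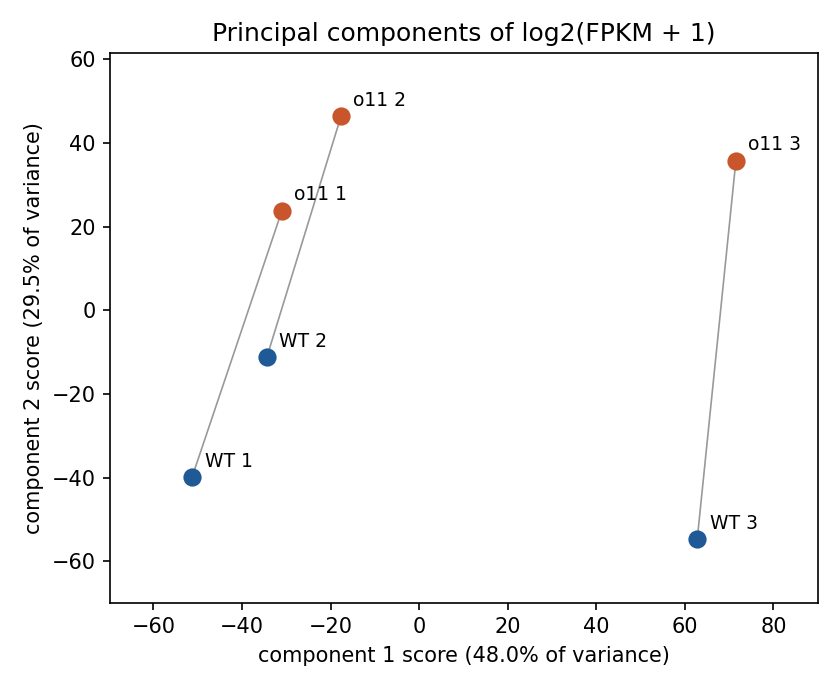
Scores of the 6 libraries on the first (x axis) and the second (y axis) principal component of log2(FPKM + 1), WT in blue and o11 in orange, with lines joining libraries of the same replicate number. The replicate 3 libraries lie at 62.8 and 71.5 on the x axis, and all o11 libraries lie above all WT libraries on the y axis.

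In o11, 116 loci rose and 61 fell (177 of 22314 tested), and most of these changes were large: 114 of the rises and 56 of the falls were at least 2-fold, and 18 rises and 2 falls at least 8-fold. With the replicate block, 2193 loci rose and 2083 fell (4276 in all), of which 657 rises and 273 falls were at least 2-fold. The balance over all sizes depended on scaling, with 2593 rises and 1703 falls after upper-quartile scaling and 2203 rises and 2384 falls after quantile normalization. All 177 loci were called in both fits with the same sign. The 8-fold changes in the blocked fit were again mostly rises, 26 against 5 falls. The median change over all tested loci was 0.00 on the log2 scale.

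The calls came from limma with Benjamini-Hochberg adjustment, and 3320 loci without and 8204 with the block had an unadjusted p under 0.05. The 3 WT and 3 o11 values did not overlap for 21.5% of tested loci. Chance gives 10%, but only for libraries that share no replicate effect, and these libraries share one. The change had the same sign in all 3 pairs for 59.1% of loci, where chance gives 25% per locus. Loci vary together within a library, so both shares are descriptive. Among the replicate 2 and 3 libraries, for which the same tools were listed, 0 loci passed without the block in limma (2219 at an unadjusted p under 0.05) and 476 with it (303 rose and 173 fell), 458 of them among the 4276. Replicate 1 holds 1 library per genotype and gives no test. Leaving out any 1 library left 2 to 14 loci without the block. With the block, 469 loci were left without WT replicate 1, 804 without WT replicate 2, 520 without o11 replicate 1 and 831 without o11 replicate 2, and 56 of the 4276 passed a test against a fold of 2.

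**Figure D2:**
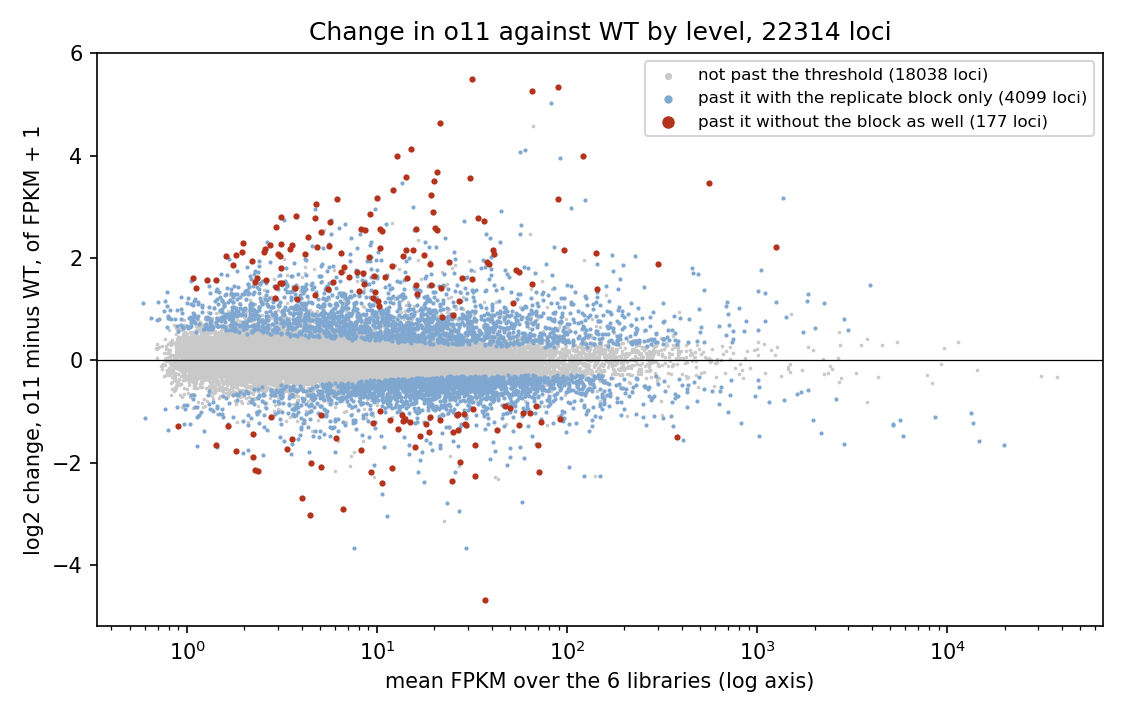
Log2 change of FPKM + 1 in o11 against WT (y axis) against the mean FPKM over the 6 libraries (x axis, log scale) for 22314 loci, each point 1 locus. Red points (177) pass the threshold in both fits, blue points only in the fit with the replicate block, and grey points in neither; the largest changes among red points are rises.

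Changed loci were found at every expression level. In the blocked fit, 1001 loci with a mean under 10 FPKM rose and 460 fell (of 11390). From 10 to 100 FPKM, 977 rose and 1424 fell (of 9865), but among changes of at least 2-fold 228 rose and 123 fell, and without the block 51 rose and 39 fell. Between 100 and 1000 FPKM, 198 rose and 178 fell (of 980), and of the 79 loci at 1000 FPKM or more, 17 rose and 21 fell. Without the block, rises and falls were 59 and 21 under 10 FPKM, 5 and 1 from 100 to 1000 FPKM, and 1 and 0 at 1000 FPKM or more. Whether the balance of rises and falls differs between levels was not tested.

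The most abundant transcripts took up less of the total in o11. Among the tested loci, the 50 with the highest mean held 38.0% ± 2.48 of the FPKM summed over tested loci in WT and 30.8% ± 2.12 in o11 (SD, n = 3), a difference of -7.19 percentage points with no overlap between the genotypes (exact permutation p = 0.1, the smallest possible). In the replicate 2 and 3 libraries alone the difference was -7.47 points. The set leaves out an untested locus on chromosome 7 (120233940 to 120236057) that was listed at 41485 and 39770 FPKM in the replicate 1 libraries of WT and o11 and at 0 in the other 4. With the sum over all loci of the files as the denominator the difference was -7.11 points. Seed storage proteins are among the most abundant transcripts of cereal endosperm, but which of these loci encode them was not determined. With the block, 14 of the 50 fell and 8 rose. Without it limma called 0 of the 50, with 8 at an unadjusted p under 0.05. As a set, the 50 did not pass the test against other loci (camera p = 0.0912 without and 0.0813 with the block, and p = 0.641 and p = 0.534 with an estimated correlation).

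Of 5 clusters of abundant neighbouring loci, 3 were lower in o11. A cluster of 5 loci on chromosome 7 (18755936 to 18955697, B73 RefGen_v3) summed to 64195 ± 11829 FPKM in WT and 23084 ± 10737 in o11 (SD, n = 3), a 2.78-fold lower level. A cluster of 3 loci on chromosome 4 (29951761 to 30091004) summed to 29764 ± 1907 and 12395 ± 2407 FPKM, 2.40-fold lower in o11. Another chromosome 4 cluster of 5 loci (5521259 to 5561370) summed to 44952 ± 11634 and 23138 ± 9160 FPKM, 1.94-fold lower. Together these 13 loci, of which 12 were among the top 50, held 14.8% ± 1.83 of the FPKM summed over tested loci in WT and 6.74% ± 1.61 in o11 (SD, n = 3). The 38 other loci of the top 50 held 23.2% ± 3.20 and 24.1% ± 1.49 of the same sum. These shares are descriptive, since the 3 clusters were picked for their lower level.

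With the replicate block all 3 cluster sums fell, with log2 changes of -1.55 (SE 0.28, adjusted p = 0.0235), -1.28 (SE 0.20, adjusted p = 0.0176) and -1.0 (SE 0.24, adjusted p = 0.0471) in the order given. Within the clusters, 4 of 5, 3 of 3 and 3 of 5 loci fell in that fit. The chromosome 7 sum was lower in each pair, at -1.95, -1.60 and -1.11 for replicates 1, 2 and 3. Without the block, none of the 3 sums passed the threshold (adjusted p = 0.418, 0.362 and 0.606), and exact permutation gave p = 0.1 for each. Leaving out a replicate 1 or 2 library, no longer filtering low loci or quantile normalization ended each of the 3 calls in the blocked fit, with all sums still lower in o11. For the last-named cluster upper-quartile scaling ended the call too.

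A neighbouring chromosome 4 cluster of 8 loci (5083079 to 5177135) had nearly equal means in the 2 genotypes. It summed to 32144 ± 7197 FPKM in WT and 31812 ± 6591 in o11 (SD, n = 3; log2 change -0.01, SE 0.22, adjusted p = 0.977 with the block). With quantile normalization its value was 0.53. Of its 8 loci, 1 rose and 1 fell in the blocked fit. The log2 changes of the 8 ran from -0.86 to 2.22, with 6 of them below 0, so the near-equal sum combines unlike members. Taken within each library as a log2 difference to this cluster, the 3 lower clusters were at -1.54, -1.27 and -0.99 in o11 relative to WT, each without overlap of the genotypes. These contrasts are descriptive, since the 3 clusters were picked for their lower level and the neighbour for its near-equal level. A less abundant cluster of 3 loci on chromosome 6 (136703065 to 136883005) held 1365 ± 244 FPKM in WT and 1238 ± 175 in o11 (adjusted p = 0.381 with the block).

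**Figure D3:**
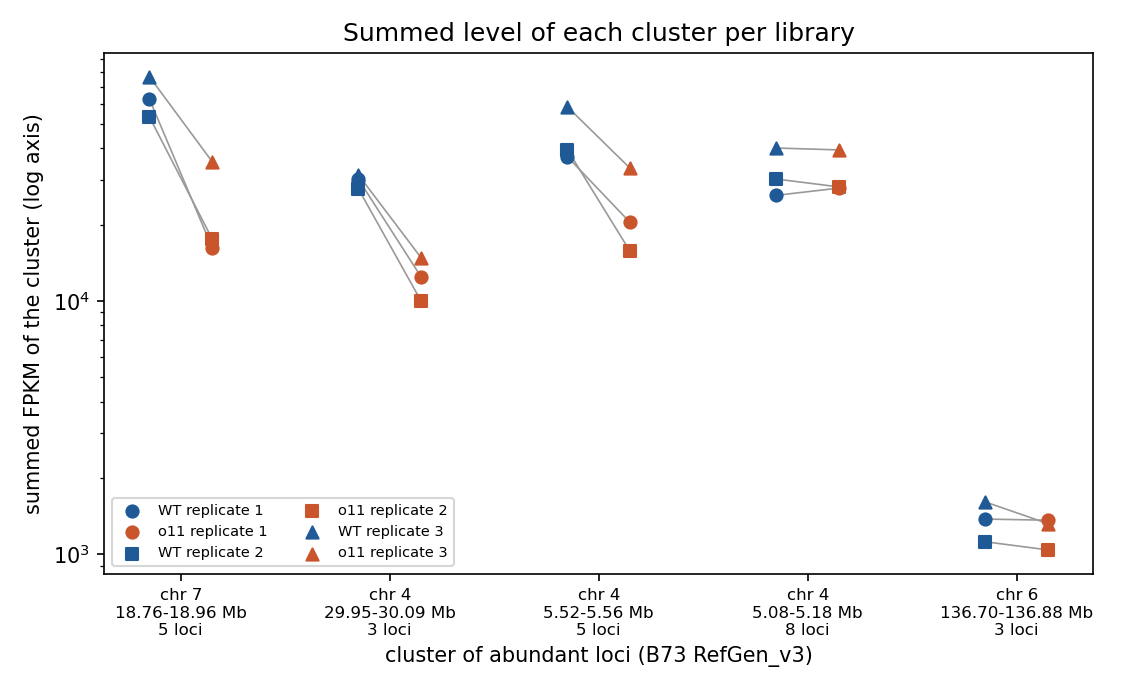
Summed FPKM (y axis, log scale) of each of the 5 clusters of abundant loci (x axis, with chromosome and position) per library, WT in blue and o11 in orange, with lines joining libraries of the same replicate number. In the 3 clusters on the left every o11 library lies below every WT library, while the 8-locus cluster on chromosome 4 has means of 32144 and 31812 FPKM.

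The largest rise was at a locus on chromosome 3 (222754576 to 222755800). Its WT libraries were at 0, 0.162 and 0.348 FPKM, and its o11 libraries at 25.3, 45.0 and 118 FPKM (log2 change 5.50, SE 0.53, adjusted p = 0.0209, and 0.00337 with the block). A locus on chromosome 6 (129268963 to 129270180) rose from 3.63 ± 2.81 to 176 ± 64.9 FPKM (SD, n = 3; log2 change 5.34, SE 0.46, adjusted p = 0.0158, and 0.00345 with the block). The largest fall on the log2(FPKM + 1) scale was at a locus on chromosome 1 (209401525 to 209403939), from 72.2 ± 26.0 to 1.89 ± 1.11 FPKM (SD, n = 3; log2 change -4.67, SE 0.34, adjusted p = 0.0107, and 0.000973 with the block). A locus on chromosome 8 (42015205 to 42018417) fell from 8.67 ± 1.83 to 0.179 ± 0.0918 FPKM (SD, n = 3; log2 change -3.02, SE 0.21, adjusted p = 0.0107, and 0.00282 with the block). By the ratio of mean FPKM, its fall was larger than that of the chromosome 1 locus (48.3-fold against 38.1-fold). With a pseudocount of 0.1 in place of 1, the log2 changes of the 4 loci were 7.82, 5.74, -5.26 and -5.00 in the order given. In the blocked fit these 4 calls held under every alternative run for them. The chromosome 3 locus is among the 42 loci with at least 50 FPKM in 1 library and 0 in another. It was thus not in the alternative that leaves such loci out, and its value at 0 can be a failed estimate. Without the block each of the 4 calls was lost when WT replicate 1 or 2 or o11 replicate 1 or 2 was left out. For 3 of the 4 this also held without a replicate 3 library. Each change kept its sign. A test against a fold of 2 also ended the 4 calls without the block (limma adjusted p = 0.0848, 0.0723, 0.0615 and 0.0648), and the replicate 1 and 2 libraries alone ended 3 of them. In the replicate 2 and 3 libraries alone the 4 changes were 5.89, 5.47, -4.60 and -3.04 (limma adjusted p = 0.239 each without the block, and 0.0211 to 0.0257 with it).

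Transcripts of the plastid and mitochondrial genomes, listed as a sign of RNA quality, were highest in replicate 2 and lowest in replicate 1 of both genotypes. Their summed FPKM was 37.0, 268 and 143 in WT replicates 1 to 3 and 35.1, 228 and 54.7 in o11 replicates 1 to 3 (exact permutation p = 0.6 between genotypes, without pairing), and the o11 library was lower in all 3 pairs. Of the 13 tested loci of the list, 0 passed the threshold in limma, over all loci or adjusted over the list alone, with 0 at an unadjusted p under 0.05 without and 5 with the block. Their median log2 change was -0.48. Leaving out 1 library, which breaks a pair, moved it to -1.11 (WT replicate 1), -1.16 (o11 replicate 2), 0.02 (WT replicate 2) or 0.01 (o11 replicate 1). With pairs kept whole it was -0.49 in the replicate 2 and 3 libraries alone and -0.30 in the replicate 1 and 2 libraries alone. Camera in limma, a set test over all loci that is not a permutation test, gave p = 0.0901 without the block and p = 0.00541 with it. With an estimated correlation these were p = 0.627 and p = 0.278, and fry gave p = 0.606 and p = 0.141.

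Loci changed at least 2-fold in the blocked fit lay on every chromosome (3.17% to 5.50% of tested loci), with a local excess in 3 windows. On chromosome 7 from 10 to 20 Mb, 18 of 114 tested loci (15.8%) had changed at least 2-fold, against 4.16% over the chromosomes, and 13 of the 18 fell. On chromosome 2, 9 of 39 loci (23.1%) between 100 and 110 Mb and 16 of 117 (13.7%) between 40 and 50 Mb had changed, most of them upward (7 and 11). The chromosome 7 window exceeded the highest window of nearly all shuffles (permutation p = 0.0006 over 205 windows), and its falls alone gave p = 0.0001, the smallest possible with 10000 shuffles. This window holds the 5-locus chromosome 7 cluster described above, of which 4 loci fell in the blocked fit. With that cluster not counted, the highest window was chromosome 2 at 100 to 110 Mb (permutation p = 0.0014). The chromosome 7 window still passed at a permutation p under 0.05. Rises alone were most enriched at 100 to 110 Mb on chromosome 2 (permutation p = 0.0053). For the 177 loci called without the block no window passed (highest window, chromosome 2 at 30 to 40 Mb, permutation p = 0.159). Shuffling treats loci as independent, which neighbouring copies of a gene are not.

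**Figure D4:**
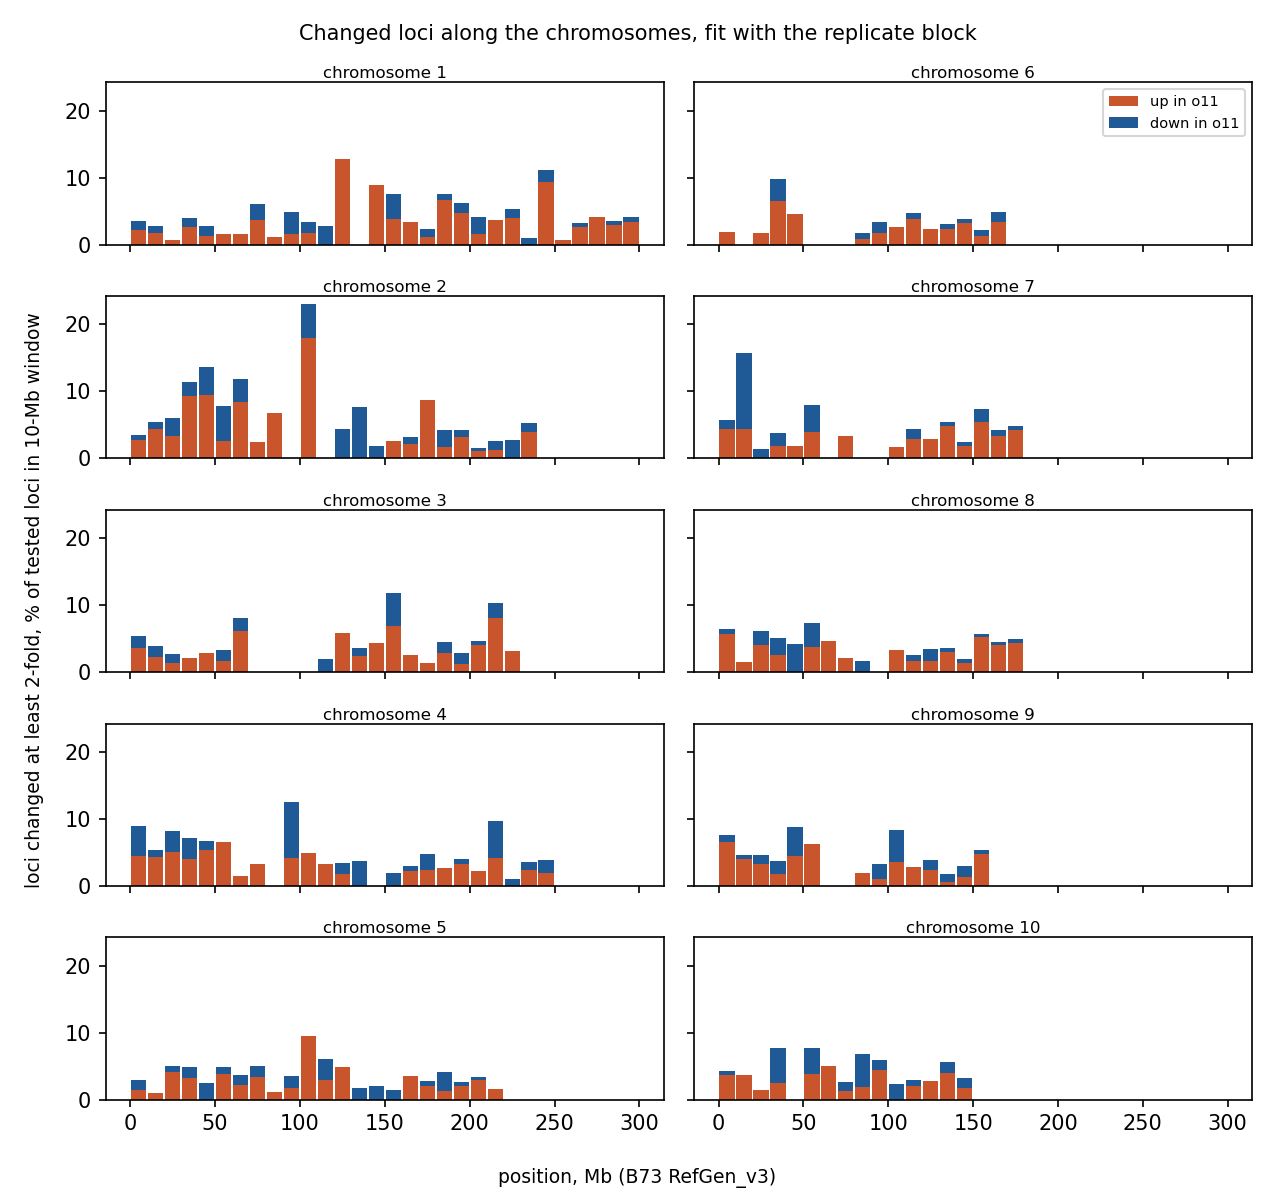
Share of tested loci that changed at least 2-fold in the blocked fit (y axis, percent) in 10-Mb windows along each chromosome (x axis, Mb), rises in orange and falls in blue stacked on them, with windows under 20 tested loci left empty. The highest bars are chromosome 2 at 100 to 110 Mb (23.1%) and chromosome 7 at 10 to 20 Mb (15.8%).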

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

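Added after the data were seen were upper-quartile scaling, the replicate 1 and 2 libraries alone, the term for replicate 3, loci of shared intervals or with values at 0 against 50 or more left out, the cluster definitions, the number of loci and the denominator of the top 50 share, and every alternative run within the blocked fit; the others had been planned. The 177 loci called without the block became 4276 with the replicate block (the paired fit), 93 with no filter on low values, 271 without the 50 most abundant loci, 430 with a term for replicate 1 and 1153 with a term for replicate 3. A test against a fold of 2 left 2, the replicate 1 and 2 libraries alone 3 and the replicate 2 and 3 libraries alone 0. Leaving out 1 library gave 2 to 14. The remaining 7 alternatives gave 122 to 248 loci. With the block, the 4276 loci became 56 in a test against a fold of 2 and 476 in the replicate 2 and 3 libraries alone. They became 469 without WT replicate 1, 804 without WT replicate 2, 520 without o11 replicate 1 and 831 without o11 replicate 2. Without WT or o11 replicate 3 they were 5163 and 5260. With fewer libraries the fit has fewer residual degrees of freedom, and a lone library of a pair adds nothing to the blocked contrast. For other shifts the cause was not tested.

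The cluster sums on chromosome 7 (18755936), chromosome 4 (29951761) and chromosome 4 (5521259), in this order throughout, stayed lower in o11 under each alternative run for them, and passed the threshold with the replicate block (-1.55, -1.28 and -1.0) but not without it, except that the second passed at an adjusted p of 0.0462 with limma and no mean-variance trend (-1.28). Within the blocked fit the sums were -0.99, -0.81 and -0.54 with quantile normalization (adjusted p = 0.117, 0.0776 and 0.279), which sets the top ranks equal between libraries. With no filter on low values they kept their size at adjusted p = 0.211, 0.145 and 0.343. The replicate 2 and 3 libraries alone gave -1.36, -1.28 and -1.07 (adjusted p = 0.114, 0.0904 and 0.158). The third was -0.95 with upper-quartile scaling (adjusted p = 0.0519). Leaving out 1 library gave -1.77 to -1.36, -1.38 to -1.18 and -1.10 to -0.83. Over all alternatives in the blocked fit the adjusted p ran from 0.0119 to 0.211, from 0.00901 to 0.145 and from 0.0215 to 0.343. The second cluster is not formed with a gap of 100 kb, and the sums were not fitted in the test against a fold of 2 or without the 50 most abundant loci. The top 50 share difference stayed between -8.38 and -5.91 points.

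For the plastid and mitochondrial list, camera's p of 0.0901 became 0.00541 with the replicate block, 0.0496 with quantile normalization, 0.0361 with no filter on low values, 0.0421 with upper-quartile scaling, 0.00534 in the replicate 2 and 3 libraries alone and 0.0231 with a term for replicate 1. These p-values use the preset correlation; with an estimated correlation p = 0.627 without and p = 0.278 with the block. Leaving out 1 library gave 0.000111 (WT replicate 1), 0.000219 (o11 replicate 2) and up to 0.774 (WT replicate 2). The list's count stayed at 0 in limma under all alternatives. The block also changed calls among the top 50 loci, windows and chromosomes. Leaving out the chromosome of the mutated gene was not run. Absolute depth is unknown, so the precision of low values could not be set.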

Other observations

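Of the tests in this part, the split counts, relative depth, the listed tools, the cluster sums, the contrasts with the neighbouring cluster and with loci of like level, the chromosome count, the window count without the chromosome 7 cluster and the loci listed at 0 were chosen after the results were seen; the others were set down before.

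A locus on chromosome 7 (120233940 to 120236057) was listed at 41485 FPKM in WT replicate 1 and 39770 in o11 replicate 1, and at 0 in the other 4 libraries. Bowtie was listed for the replicate 1 libraries, and TopHat and Cufflinks for the others. Among the 42 loci with at least 50 FPKM in 1 library and 0 in another, same-numbered WT and o11 libraries were alike in being at 0 or not in 75.4% of pairs, against 52.4% of other WT and o11 pairs. In all, 8 loci were listed at 0 in every WT library with at least 1 FPKM in every o11 library, and 4 the other way round. These 12 loci could mark transcripts switched on or off with the genotype. The other splits of the 6 libraries that part all 3 pairs gave at most 2 such loci, and the splits that keep a same-numbered pair on one side up to 10. The 4 splits that part all pairs are too few for a share under 0.05, so this on or off expression stays open.

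The 177 changed loci were compared with the other splits of the 6 libraries into 3 and 3. Only 1 of 10 splits, the real one, gave as many, and the highest other split gave 2. In the blocked fit, 1 of the 4 splits that part all 3 pairs, the real one with 4276 loci, gave as many, and the highest other split gave 0. The other 6 splits keep a same-numbered pair on one side. Both numbers of splits are too few for a share under 0.05.

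The replicate 3 libraries of both genotypes stood apart from the other 4 on component 1 (48.0% of the variance). Depth is argued against, since the relative depth of 2 of 2 replicate 3 libraries lay inside the range of the other 4. These depths are estimates without a spread, from the 334 of 2591 (WT) and 397 of 2845 (o11) low loci that lay on the step. Scaling by a few abundant loci is argued against by the correlation of the 2 replicate 3 deviations, which was 0.758 after quantile normalization without the 50 most abundant loci. A strong dependence on genomic span is argued against (Spearman rho of the shift with span -0.0864 in WT and -0.127 in o11). A weak one in the same direction in both genotypes is not excluded, and transcript length was not tested. The listed tools part replicate 1 from the others, not replicate 3. Replicates 2 and 3 correlated less well than replicates 1 and 2, by -0.0407 in o11, the value nearer 0. That restates the pattern and is no separate test of the tools. A shared day, ear or growth condition of the numbered pairs may remain, and was not tested, since no label describes it.

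The 3 clusters of abundant loci were lower in o11 while the 8-locus cluster close to one of them on chromosome 4 was not. Reads moved between near-identical copies inside a cluster would leave its sum unchanged and raise some members. In the blocked fit the sum nearest 0 was at -1.0, but the clusters were picked for lower sums, so its sign was set beforehand. No member was higher in o11: the highest log2 changes of a member were -0.80, -1.21 and -0.43. Reads moved to loci outside a cluster were not tested. The median change over all tested loci, 0.00, argues against a single scaling factor per library, which would move all loci alike. The contrast with the neighbouring cluster, -0.99 for the cluster nearest 0, cannot decide this. Its sign was set when the clusters were picked for falling or not. For a scaling that differs by expression level, the members of each cluster were set against the 4 loci nearest in mean level outside these clusters. Those loci changed by 0.01, 0.08 and 0.07 on average, so no such shift was seen in them. In o11 relative to WT the members differed from them by -1.43 (SE 0.47 over the 3 pairs), -1.38 (SE 0.10) and -0.97 (SE 0.18) on the log2 scale. The sign of these differences was set by picking the clusters for their fall. Quantile normalization sets the top ranks equal by construction and so cannot decide on scaling. It left the sums at -0.99, -0.81 and -0.54 in the blocked fit (limma adjusted p = 0.117, 0.0776 and 0.279). A dependence of these clusters on the o11 genotype may account for the pattern, as a hypothesis. A count of molecules would test whether the level is lower. It would not tell an effect of the mutation from that of a linked segment from another parent, which was not tested for these clusters.

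Changed loci lay on every chromosome, with an excess on chromosome 7 from 10 to 20 Mb and on chromosome 2. A linked segment from another parent around the mutated gene may give such windows, with neighbouring windows raised together. The highest window had a permutation p of 0.0006, but the 3 windows at a permutation p under 0.05 were not adjacent. Chromosome 2 at 30 to 40 Mb (16 of 140 loci, 11.4%), beside the window at 40 to 50 Mb, narrowly missed that limit. A linked segment therefore cannot be told apart from separate gene clusters. The falling 5-locus cluster lies inside the chromosome 7 window. When this cluster was not counted, 4 windows passed, with neighbours on chromosome 2 among them. The chromosome 7 window was still 1 of the 4, so the cluster alone does not make up its excess. The highest was chromosome 2 at 100 to 110 Mb (permutation p = 0.0014). Chromosome 2 as a whole held 145 changed of 2634 loci (5.50% against 4.16%; permutation p = 0.0026), while the fit without the block gave 27 of 2634 (permutation p = 0.656). Of the 145, 61 (of 530 loci, 11.5%) lay between 30 and 110 Mb, bounds chosen after the windows were seen, and 84 (of 2104 loci, 3.99%) elsewhere on it.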
